A study of Mus musculus with 6 samples.

How the data were processed

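Total RNA from 6 mouse CD4 T cell cultures was labelled with a 3' in vitro transcription kit and hybridized to Affymetrix arrays, 1 array per sample, per the labels' protocols. The cultures crossed 2 genotypes (wild type and Ezh2 KO) with 3 conditions. Naive cells were plated with 10 µg/ml antibody to the T cell receptor, 1 µg/ml antibody to CD28 and 15 ng/ml IL-2, and cultured for 5 days in all, 2 with and 3 without the antibodies, per the labels. Th1 cultures had 1 ng/ml IL-12 and Th2 cultures 10 ng/ml IL-4. The authors' deposited values are intensities on a linear scale, 1 per probe set and array, and Affymetrix Expression Console is named, with no version, per the submitters' processing notes. The summarization algorithm is not given in the sources used here. In the deposited intensities, the mean after trimming 2% at each end was 500.003 on every array, so the arrays had been scaled to one target, and their distributions were not identical, so they had not been quantile normalized. Values ran from 0.0858 to 59718.5.

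The file holds 45101 probe sets, of which 64 are controls. The platform's annotation table gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160. Its Entrez identifiers were found in the RefSeq table of assembly GRCm38.p6 for 34741 of the named probe sets, and 0 symbols needed an update. That table served only for names and for the order of genes along chromosomes. Probe sets with several symbols or none entered no gene test.

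Values were raised to a floor at the 20th percentile of all values (intensity 11.33, log2 3.50) and taken to log2. The probe set with the highest mean stood for each of 18193 genes, and a gene was tested where its highest value reached the median of all values (64.43), which left 11572 genes. A log2 difference understates the change of a gene at the floor, and a fold is given as a lower bound where any array of the lower genotype was at the floor. Signal over background, not depth, limits dim genes. With limma 3.58.1 in R 4.3.3, an additive model of culture and genotype was fitted to all 6 arrays, which leaves 2 residual degrees of freedom, moderated with eBayes (prior degrees of freedom 1.66) and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The genotype effect had culture as a block. Th1 against Th2 and each against unpolarized came from the same fit, with genotype as a block. Differences within 1 culture or within 1 genotype have no replicate and no test.

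A collection of 31 gene lists, fixed before the data were examined, covered helper T cell fates (Th1, Th2, Th17, Treg, Tfh, naive and memory), cytotoxic and NK receptor genes, cytokines and chemokines, receptors, inhibitory receptors, lineage factors, developmental factors, the Cdkn2 locus, PRC2, PRC1 with H3K27 demethylases, proliferation, apoptosis and p53, stress, interferon response, activation, glycolysis, sterol synthesis, and markers of B, CD8, CD4, NK and NKT, myeloid, mast, erythroid and gamma delta T cells and of sex. The 26 lists with at least 3 tested genes went through camera (two-sided, preset inter-gene correlation 0.01), with an estimated correlation and fry beside it. With an estimated correlation, camera uses the 2 residual degrees of freedom, so few lists could pass. It also lost lists whose estimated correlation was under the preset, such as the myeloid markers (-0.114, camera adjusted p 0.01159 against 0.377). Failing it therefore does not show that correlated genes made the call. Per culture, list medians were set against 10000 random lists drawn from 20 bins of mean expression.

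The genes named were fixed by rule before the data were examined. They are Ezh2 and 8 core genes (Ifng, Tbx21, Eomes, Il4, Il5, Il13, Il10, Gata3); the 10 highest and 10 lowest mean differences among genes past the threshold with one sign in all pairs, or, where fewer passed, as values only, those at 2-fold or more in every pair; the 5 highest and 5 lowest of each untested difference; and up to 4 members of each list with the largest differences. Predicted genes, clone names and receptor segments were left out. Klrd1, Klrc1, Prf1, Fasl and Gzmb, and the genes outside the lists in the closing observations, were chosen after their values were seen.

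On simulated data made from the arrays' own means and spread, the genotype test recovered 26.5% of 200 genes changed by log2 1, 77% at log2 2 and 86% at log2 4, with 3, 4 and 6 false calls. With 2000 genes changed by log2 2 it recovered 90.6%, with 93 false calls. The list test found 20 of 20 lists shifted by log2 1 and called 8 of 445 untouched ones. Each simulated gene was drawn independently, whereas estimated correlations within the real lists reached 0.712 (sterol synthesis genes). That rate of false list calls therefore does not carry over to the arrays. Alternatives were median centring, quantile normalization, no filter or a filter at the 60th percentile of the mean, no floor or a floor at the 40th percentile, other rules for probe sets, no block, a trended robust prior, and leaving out pairs or arrays. Ratios of the 5' to the 3' probe sets of actin ran from -0.26 to -0.20 on the log2 scale and those of Gapdh from 0.26 to 0.35. Permutation, neighbour and figure steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.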

Results

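Gene expression was measured with 6 Affymetrix 3' expression arrays, 1 for each combination of 2 genotypes and 3 culture conditions. Naive CD4 T cells from mouse spleen, labelled wild type or Ezh2 knockout (Ezh2 KO), were activated for 2 days with plate-bound antibody to the T cell receptor plus antibody to CD28 in IL-2, and then kept for 3 more days without these antibodies. Ezh2 is the main catalytic subunit of Polycomb repressive complex 2 (PRC2), which places methyl groups on lysine 27 of histone H3, a mark of silent genes. Th1 cultures contained IL-12 and an antibody blocking IL-4. Th2 cultures contained IL-4 and an antibody blocking interferon gamma, and unpolarized cultures contained both blocking antibodies. All arrays carried the same trimmed mean intensity of 500.003, with medians from 61.3 to 69.1, and 11572 genes had enough signal to be tested. Because each group had 1 array, differences are given per culture, or as the mean ± SD over the 3 cultures (n = 3 pairs of arrays), and the number of arrays limits their precision. The labels do not say whether the arrays of one genotype came from separate mice, so the p-values measure only the spread between these arrays. Since the 3 pairs are different cultures, that spread holds array noise and any difference of the genotype effect between cultures. A gene whose genotype effect depends on culture can fail the test for that reason.

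The targeted gene came first. The Ezh2 probe set read 7002, 6553 and 7677 in the wild type unpolarized, Th1 and Th2 cultures, and 4971, 4876 and 4946 in the matching Ezh2 KO cultures. The log2 difference was -0.52 ± 0.11 (SD, n = 3), 1.43-fold lower in Ezh2 KO and the same way in each culture, with a limma adjusted p of 0.0437. That call was lost with median centring (adjusted p = 0.0922), without the low filter (adjusted p = 0.0881) and with any 1 culture left out (adjusted p = 0.14 to 0.167). Much Ezh2 signal therefore remained in the arrays labelled Ezh2 KO. The labels do not say which part of the gene was deleted, and a probe set outside that part would check nothing.

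The first comparison asked which genes differ between Ezh2 KO and wild type cells across the 3 cultures. The largest rise was in Gzma, the serine protease granzyme A of cytotoxic cells, which went from intensities of 29.1, 51.7 and 51.0 in wild type to 13070, 15530 and 38610 in Ezh2 KO. Its log2 difference was 8.87 ± 0.67, or 468-fold over wild type readings that were all under the low-signal limit of 64.43, so the size of this fold is uncertain. Maf, a transcription factor of Th2 and IL-10-producing T cells, rose 79.3-fold (log2 6.31 ± 0.54), Ifitm1, an interferon-inducible membrane protein, 51.2-fold, the chemokine receptor Cxcr6 39.4-fold and the fibrinogen-like protein Fgl2 37.9-fold. Igsf5 and granzyme D (Gzmd) were at the floor on all wild type arrays and rose at least 54.6-fold and at least 47.3-fold. Tmem163 rose at least 41.8-fold, Gcnt2 35.4-fold and uridine phosphorylase Upp1 34.1-fold, the last 2 again over wild type readings under that limit. Among the genes that fell, Csn2, a milk casein, was at least 24.3-fold lower (log2 -4.60 ± 0.43), Morc1, a gene known for its role in the male germ line, 19.7-fold lower with all Ezh2 KO readings under the same limit, Cdhr3 at least 12.7-fold, Stxbp6 12.7-fold lower and Dapl1, a transcript of naive T cells, 11.5-fold lower. Lratd1, at the floor on all Ezh2 KO arrays, was at least 8.81-fold lower, Cpe 8.16-fold, the DNA repair enzyme Mgmt at least 8.07-fold, Ccn3 6.85-fold and Tmie at least 6.55-fold lower.

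In all, 966 genes were higher and 924 lower in Ezh2 KO (limma with culture as a block, Benjamini-Hochberg adjusted p under 0.05). Each of these 1890 genes had the same sign in all 3 cultures, which a test that divides by the spread over the cultures nearly requires. Large changes were mostly rises: 543 higher and 217 lower genes differed by 2-fold or more, and 65 higher and 6 lower genes by 10-fold or more. The counts lie close to the limit of the test. Without a filter on low values, and with any 1 culture left out, 0 genes passed, although 4711 and 2952 to 3227 genes then had an unadjusted p under 0.05, against 4479 in the full set. With each array centred on its median the split was 868 higher and 413 lower.

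**Figure D1:**
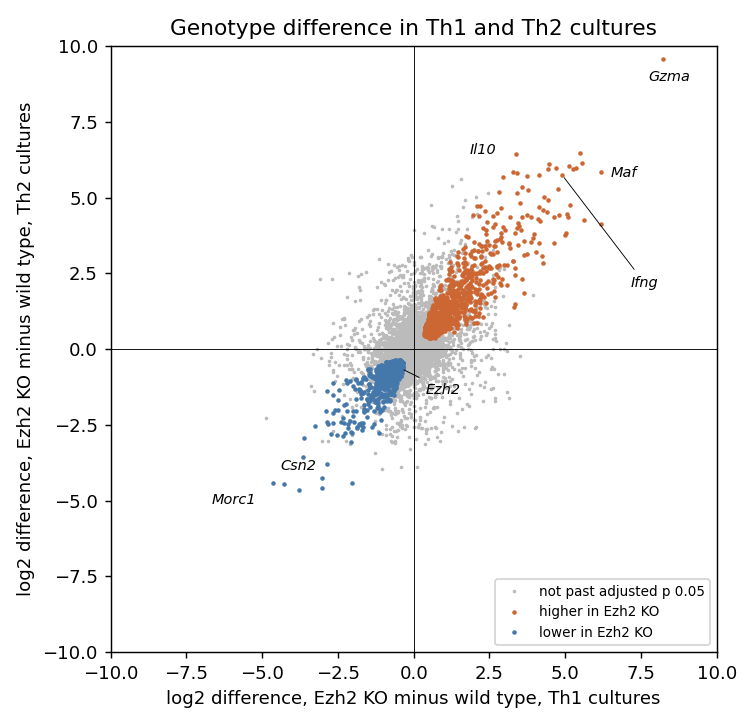
Log2 difference of Ezh2 KO minus wild type for each of 11572 tested genes (points), in Th1 cultures on the horizontal axis and in Th2 cultures on the vertical axis. Genes past adjusted p 0.05 over the 3 cultures are orange (966 higher) or blue (924 lower), and Gzma stands alone at 8.23 in Th1 and 9.56 in Th2 cultures.

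Genes of cytotoxic cells had the largest median difference of the lists with at least 3 tested genes. Of 18 tested cytotoxic and NK receptor genes, 15 rose in Ezh2 KO and 0 fell (16 higher when adjusted over the list alone), with a list median of 2.85 on the log2 scale. Besides Gzma and Gzmd, granzyme G (Gzmg) rose by at least 4.95 ± 0.87, the granule protein gene Nkg7 by 4.85 ± 1.37, the NK receptor chains Klrd1 by 4.84 and Klrc1 by at least 3.77, perforin (Prf1) by 2.98 and Fas ligand (Fasl) by 2.35. Granzyme B (Gzmb), not among the 15, was already bright in wild type unpolarized, Th1 and Th2 cultures (25350, 32780 and 20190). In the matching Ezh2 KO cultures it read 52930, 43230 and 54390. The list passed camera with the preset correlation (adjusted p = 1.331e-10) and not with an estimated correlation (0.453, adjusted p = 0.38). The latter version rests on 2 residual degrees of freedom and passed 0 of 26 lists, so here and below a miss decides little. Of the 8 NK and NKT cell markers 7 had a named probe set. Only Cd160, up by 3.71 ± 0.33, and the receptor adaptor Fcer1g, up by at least 2.05 ± 0.55, had enough signal to test. The NK adaptor Tyrobp read 36.3, 51.2 and 48.9 in wild type and 37.2, 31.6 and 32.2 in Ezh2 KO, all under the low-signal limit of 64.43. The CD8 chains gave -0.49 ± 0.28 for Cd8a and 0.35 ± 0.36 for Cd8b1, neither past the threshold.

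Signature genes of opposing helper T cell fates were both higher in Ezh2 KO. Ifng, which encodes interferon gamma, the signature cytokine of Th1 cells, rose at least 33.5-fold (log2 5.07 ± 0.61, adjusted p = 0.0177), and the T-box factor Eomes rose 5.57-fold (log2 2.48 ± 0.27). Il4, the signature cytokine of Th2 cells, rose 6.31-fold (log2 2.66 ± 1.09, adjusted p = 0.045). Its wild type readings in unpolarized and Th1 cultures were under the low-signal limit, so this fold is uncertain. In Th2 cultures Il4 went from 227.5 in wild type to 601.4 in Ezh2 KO. Il10, an inhibitory cytokine, rose 21.7-fold (log2 4.44 ± 1.73) over wild type readings under the low-signal limit. The Th2 cytokines Il5 (at least 2.56 ± 2.10, adjusted p = 0.132) and Il13 (at least 3.31 ± 2.08, adjusted p = 0.086), the Th1 factor Tbx21 (1.59 ± 1.15, adjusted p = 0.108) and the Th2 factor Gata3 (0.84 ± 0.36, adjusted p = 0.0559) did not pass, though each was higher in all 3 cultures. Of 24 Th1 genes, 16 rose and 0 fell (21 higher when adjusted over the list alone), among them the chemokine Ccl5 at 4.12 ± 0.66. Of 21 Th2 genes, 8 rose and 0 fell (11 higher and 1 lower when adjusted over the list alone), among them Pparg, a nuclear receptor, at 4.15 ± 0.13 and the cytokine Csf2 at 3.57 ± 0.07. Wild type Pparg read under the low-signal limit in unpolarized and Th1 cultures and 64.87 in Th2 cultures, so its size is uncertain. Of 4 Th17 genes, 3 rose (4 when adjusted over the list alone): the aryl hydrocarbon receptor Ahr at 4.52 ± 0.23, over wild type readings under the low-signal limit, Rora at 1.09 ± 0.30 and Batf at 1.07 ± 0.29. The Th1, Th2 and Th17 lists passed camera with the preset correlation (adjusted p = 1.577e-11, 2.643e-06 and 0.0006143), and none did with an estimated correlation (adjusted p = 0.38, 0.377 and 0.377). Beside these lists, the mast cell and basophil markers did not pass (adjusted p = 0.57; 2 of 3 higher and 1 lower when adjusted over the list alone), with values of at least 3.23 ± 2.06 for Cpa3, a mast cell protease also known in Th2 settings, 1.16 ± 0.78 for Kit and a fall by 1.85 ± 0.75 for Gata2, which read under the low-signal limit on all Ezh2 KO arrays. The activation induced genes gave a median of 0.23 (adjusted p = 0.0789, or 0.00152 with the mean of all probe sets of a gene, 0.414 with an estimated correlation and 0.052 with fry), with 5 of 21 higher and 3 lower (7 higher and 4 lower when adjusted over the list alone), led by Ier3 at 1.92 ± 0.46.

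**Figure D2:**
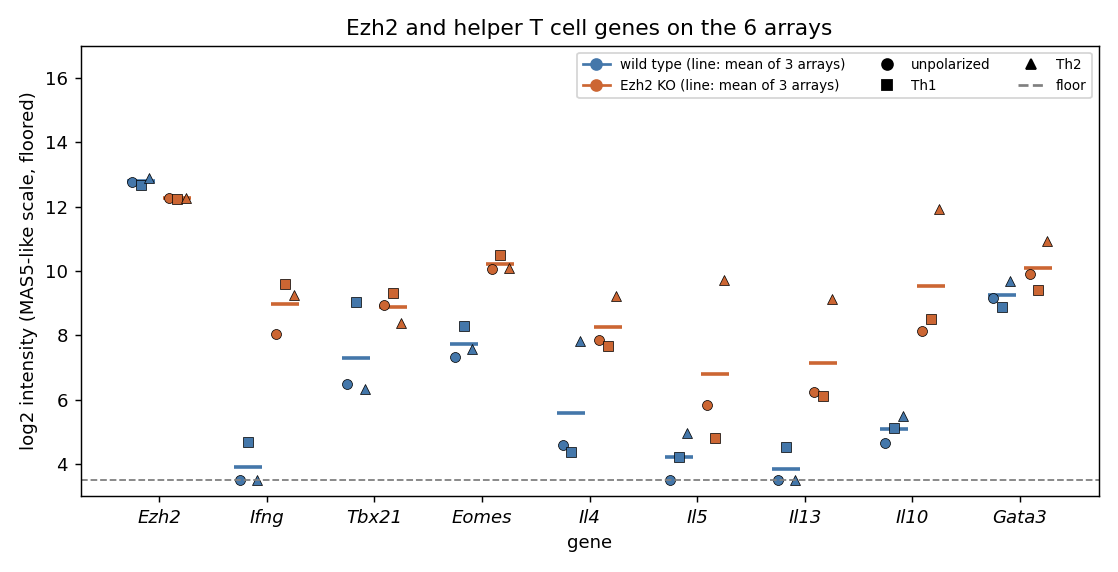
Log2 intensity of Ezh2 and 8 helper T cell genes on each of the 6 arrays (vertical axis), with wild type in blue and Ezh2 KO in orange, circles for unpolarized, squares for Th1 and triangles for Th2 cultures, bars for the mean of 3 arrays and a dashed line for the floor of 3.50. Ifng lay between 8.06 and 9.58 in Ezh2 KO and between 3.50 and 4.69 in wild type, while Ezh2 itself differed by 0.52.

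Genes of cytokines, their receptors and lineage factors also changed. The gene lists overlap, so their results are not separate support. Cd244a, an inhibitory receptor below, is also in the cytotoxic list, and Eomes is in the cytotoxic and developmental lists. Of 28 cytokine and chemokine genes, 11 rose and 0 fell (16 higher when adjusted over the list alone), including Ccl3 at 3.72 ± 1.26 or more. Of 28 chemokine and cytokine receptor genes, 12 rose and 2 fell (18 and 3 when adjusted over the list alone), with Ccr2 up by 4.36 ± 0.29 and Cxcr4 up by 2.33 ± 0.68. Of 24 T cell lineage transcription factors, 8 rose and 2 fell (13 and 5 when adjusted over the list alone), with Zbtb32 up by 2.64 ± 0.55 and Prdm1, which encodes the effector factor Blimp-1, up by 2.41 ± 0.73. Of 9 inhibitory receptor genes, 4 rose and 0 fell (4 and 1 when adjusted over the list alone): Havcr2, which encodes TIM-3, by at least 4.08 ± 0.67, Cd244a by at least 3.73 ± 0.30, Cd160, and the ectonucleotidase Entpd1 by 2.14 ± 0.37. These lists passed camera with the preset correlation (adjusted p = 2.12e-08, 7.828e-07, 0.003922 and 0.03548). With an estimated correlation none did (adjusted p = 0.377 for the first 3 and 0.414 for the inhibitory receptors).

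The Cdkn2 locus, a classical Polycomb target that encodes inhibitors of the cell cycle, was among the strongest rises. Cdkn2b rose at least 32.2-fold (log2 5.01 ± 1.15) and Cdkn2a 23.1-fold (log2 4.53 ± 0.98), both over wild type readings under the low-signal limit. With the p53 target Cdkn1a, up by 1.79 ± 0.57, they made 3 higher genes of 7 in the list, and Cdkn1b fell by 0.71 ± 0.09 (4 higher and 1 lower when adjusted over the list alone). Of 18 apoptosis and p53 genes, 7 rose and 0 fell (11 and 1 when adjusted over the list alone), among them the pro-death genes Pmaip1 at 2.21 ± 0.30 and Bcl2l11 at 1.32 ± 0.27. Of 31 proliferation genes, 0 rose and 4 fell (12 lower when adjusted over the list alone), with the mitotic kinases Bub1 down by 0.74 ± 0.10, Bub1b by 0.68 ± 0.04 and Aurkb by 0.61 ± 0.18. Of 13 stress response genes, 3 rose (3 when adjusted over the list alone): Atf3 by 2.42 ± 0.53, Sesn2 by 1.08 ± 0.39 and the chaperone Hspa5 by 0.67 ± 0.14. The 4 lists passed camera with the preset correlation (adjusted p = 0.04649, 4.452e-05, 0.0001519 and 0.04649), but the stress list did not with median centring (adjusted p = 0.0608), without the low filter (adjusted p = 0.0727) or with fry (adjusted p = 0.169). With an estimated correlation none passed (adjusted p = 0.39, 0.377, 0.414 and 0.67).

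Genes of the Polycomb machinery itself changed singly. Of 11 PRC2 subunit genes, 1 rose and 1 fell (the same counts when adjusted over the list alone): Jarid2 by 0.59 ± 0.18 and Ezh2. Of 17 PRC1 subunit and H3K27 demethylase genes, 1 rose and 3 fell (1 and 6 when adjusted over the list alone), with Bmi1 4.53-fold higher (log2 2.18 ± 0.16), Phc1 lower by 1.12 ± 0.42 and Cbx7 lower by 0.93 ± 0.19, the last with the opposite sign (0.12) when all its probe sets were averaged. Neither list passed camera (adjusted p = 0.556 and 0.354), though the PRC2 list passed fry (adjusted p = 0.0409). With an estimated correlation neither passed (adjusted p = 0.678 and 0.586). Classical Polycomb targets among developmental transcription factor genes were mostly too dim, with 16 of 98 tested. Of these 2 rose and 1 fell (3 and 2 when adjusted over the list alone): Eomes and Lhx2, at 1.68 ± 0.71 over wild type readings under the low-signal limit, were higher, and the list did not pass (adjusted p = 0.596, median -0.13, mean 0.22). When all probe sets of a gene were averaged the list passed (adjusted p = 0.018). With an estimated correlation, on the main values, it did not (adjusted p = 0.686).

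Interferon response genes were higher in Ezh2 KO. Of 30 tested, 14 rose and 0 fell (27 when adjusted over the list alone), with a median of 1.74. The antiviral genes Rsad2 at 3.46 ± 1.11, Mx1 at 3.23 ± 1.23 and Ifit1 at 3.09 ± 0.77 and the chemokine Cxcl10 at 3.06 ± 0.83 or more led the list. It passed camera with the preset correlation (adjusted p = 1.577e-11), not with an estimated correlation (adjusted p = 0.414) and not fry (adjusted p = 0.0721). Sterol synthesis genes were lower: 10 of 15 fell and 0 rose (14 lower when adjusted over the list alone), with a median of -0.94. Lss fell by 1.48 ± 0.20, Mvd by 1.44 ± 0.26 and Msmo1 by 1.32 ± 0.18. This list too passed with the preset correlation (adjusted p = 8.388e-07), not with an estimated correlation (adjusted p = 0.414). Glycolysis genes gave a median of -0.17 (adjusted p = 0.0589), and Pdk1, down by 0.75 ± 0.21, was the 1 of 15 that fell (0 when adjusted over the list alone). The list passed without the filter on low values (adjusted p = 0.0201), and on the main values not with an estimated correlation (adjusted p = 0.678).

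Some myeloid and dendritic cell markers also moved with genotype. Of 9 tested, 3 rose and 0 fell (4 when adjusted over the list alone): the MHC class II chain H2-Aa by 4.13 ± 0.72, its invariant chain Cd74 by 1.74 ± 0.13 and Mpeg1, at the floor on all wild type arrays, by at least 2.96. The 6 others did not pass: Cd68 and Cst3 were higher in each culture, Csf1r lower in each, and H2-Ab1, Fcgr1 and Adgre1 went both ways. Lyz2, Itgam, Itgax, Cd14, S100a8 and S100a9 read under the low-signal limit on all 6 arrays. The list passed with the preset correlation (adjusted p = 0.01159), not with an estimated correlation (adjusted p = 0.377). Of 4 B cell markers, Ms4a1 rose by 2.46 ± 1.05 and Ighm fell by 0.79 ± 0.17 (2 higher and 1 lower when adjusted over the list alone), and the list passed camera only with the mean of all probe sets of a gene (adjusted p = 0.0311, against 0.345), and not with an estimated correlation (adjusted p = 0.576). Ighm had the opposite sign (0.10) when all its probe sets, most of them dim, were averaged. Its other bright probe set was lower in each Ezh2 KO culture: 3564, 3514 and 3613 in wild type against 3123, 2459 and 2024. Of 8 CD4 T cell markers only Cd2 passed, down by 0.64 ± 0.13 (3 higher and 3 lower when adjusted over the list alone), and Cd4 gave -0.55 ± 0.32. The CD4 list (adjusted p = 0.588, median 0.19, mean -0.04) did not pass. Of 2 tested gamma delta T cell markers, Cd163l1 rose by 1.57 ± 0.39. Of 8 erythroid markers 4 had a named probe set, and 0 of these had enough signal. Xist read from 20650 to 31260 on the 6 arrays, with a difference of -0.34 ± 0.15 that did not pass (1 lower when adjusted over the list alone). Its other bright probe sets, not used in the test, were lower in each Ezh2 KO culture: 16670, 15710 and 15480 against 9650, 10070 and 8647, and 5433, 6162 and 6605 against 3779, 3650 and 3098.

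Genes of other T cell states changed singly. Of 14 naive and memory T cell genes, 1 rose and 3 fell (3 and 4 when adjusted over the list alone), with Dapl1 and the lymph node homing receptor Ccr7, down by 1.00 ± 0.17, among those that fell. Of 15 Treg genes, Entpd1 rose, and 2 fell, with Gpr83 down by 1.64 ± 0.23 (1 higher and 2 lower when adjusted over the list alone). Of 7 Tfh genes, Cd200 fell by 1.24 ± 0.38 (2 lower when adjusted over the list alone). None of these lists passed (adjusted p = 0.556, 0.97 and 0.938).

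**Figure D3:**
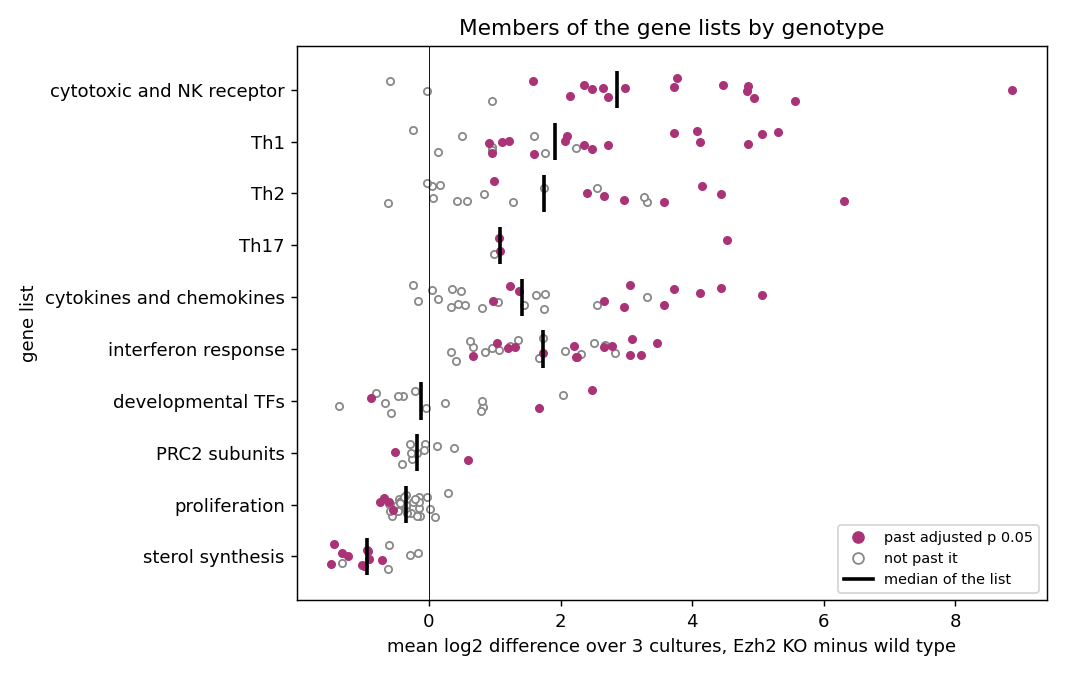
Mean log2 difference over the 3 cultures, Ezh2 KO minus wild type, of the tested members (points) of 10 gene lists (rows), filled where adjusted p was under 0.05, with a bar at each list's median. The medians run from 2.85 for the cytotoxic and NK receptor genes to -0.94 for the sterol synthesis genes.

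Within single cultures no test was possible, and the differences describe these arrays. Ezh2 KO exceeded wild type by 2-fold or more for 874 genes in unpolarized, 842 in Th1 and 1112 in Th2 cultures, and was lower by 2-fold or more for 671, 511 and 692 genes. Gzma led each culture, at 8.81, 8.23 and 9.56 on the log2 scale. After it came Maf (6.90), Tmem163 (5.85), Upp1 (5.73) and Igsf5 (5.63) in unpolarized cultures. In Th1 cultures they were Tmem163 (6.19), Maf (6.18), Cdkn2a (5.61) and Igsf5 (5.55), and in Th2 cultures Ifitm1 (6.48), Il10 (6.43), Igsf5 (6.13) and Fgl2 (6.12). The lowest were Csn2 (-5.08) in unpolarized, Matk (-4.86) in Th1 and Stxbp6 (-4.59) in Th2 cultures. The values of Igsf5, of Tmem163 in Th1 cultures, of Csn2 and of Matk are bounds, because the lower reading was at the floor. Those of Gzma, Upp1, Cdkn2a and Il10, and of Maf and Tmem163 in unpolarized cultures, were taken over readings under the low-signal limit, so the order of these genes is not firm. The Ezh2 KO minus wild type difference correlated across genes between cultures, with Pearson r of 0.61 for unpolarized and Th1, 0.65 for unpolarized and Th2 and 0.67 for Th1 and Th2. Genes are not independent replicates, and the 3 differences share no array. Of the genes higher by 2-fold, 505, 612 and 579 were shared between these pairs of cultures, where independent lists would share 63.6, 84.0 and 80.9. The median of the cytotoxic list was above all of 10000 random lists matched on mean expression in each culture, and so were those of the Th1, Th2 and interferon response lists, while the sterol synthesis list was below all of them in each.

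The second set of comparisons asked what the polarizing cultures changed across both genotypes. The Th1 minus Th2 differences of the core genes ran in the textbook direction for most: 1.83 (SE 0.61) for Tbx21, 0.76 (SE 0.33) for Ifng, 0.56 (SE 0.17) for Eomes, -2.51 (SE 0.58) for Il4, -2.83 (SE 1.10) for Il5, -0.99 (SE 1.09) for Il13, -1.90 (SE 0.91) for Il10 and -1.16 (SE 0.21) for Gata3. The largest differences seen in both genotypes were higher in Th1 cultures for Inhbb (3.36) and Insc (2.72), and lower for Mapk12 (-3.15), the enkephalin precursor Penk (-2.96), Col18a1 (-2.73), Cyp11a1 (-2.70), a steroid-making enzyme, and Cd24a (-2.62). In Th2 cultures Inhbb and Insc, in Th1 cultures Mapk12 and, in wild type, Ifng, Il5, Il13 and Il10 in both read under the low-signal limit. So did Il4 and Penk in wild type Th1 and Il5 in Ezh2 KO Th1 cultures, and these sizes are uncertain. None of these genes passed. With limma, 0 genes differed between Th1 and Th2 cultures, 0 between Th1 and unpolarized and 0 between Th2 and unpolarized, with 878, 632 and 775 genes at an unadjusted p under 0.05 and smallest adjusted p values of 0.255 (Susd5), 0.497 and 0.453. The contrasts with unpolarized cultures share those 2 control arrays. With a trended and robust prior 31 genes passed for Th1 against Th2 and 13 for Th2 against unpolarized. In simulations, Th1 against Th2 recovered 69.5% of genes changed by log2 2 and 0% of those changed by log2 1.

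Under the preset correlation 8 of 26 gene lists passed camera for Th1 against Th2 cultures. The same test called 4, 11 and 6 lists in the splits of the arrays that exchange genotype labels within 1 culture. Those splits hold part of the genotype effect and concern another contrast, so they give no chance level for this count. Its strength as evidence is thus unknown. The Th1 genes were higher in Th1 cultures (median 0.46, adjusted p = 0.0002154), as were the interferon response genes (median 0.65, adjusted p = 1.48e-07, but 1.39 in wild type and -0.01 in Ezh2 KO) and the developmental transcription factor genes (0.47, adjusted p = 0.01519). The Th2 genes were lower (median -0.99, adjusted p = 4.367e-08), as were the Th17 (-0.41, adjusted p = 0.03709), Treg (-0.26, adjusted p = 0.01519), B cell (-1.04, adjusted p = 0.009889) and myeloid (-0.39, adjusted p = 0.02256) lists. Without the low filter 4 lists passed, and with fry 0. With an estimated correlation none passed, with an adjusted p of 0.819 for the Th1 and interferon lists, 0.668 for the Th17 list and 0.541 for the other 5. Over the lists alone, 4 Th2 genes, 1 B cell marker and 1 myeloid marker were lower and 0 Th1 genes passed (adjusted over the list alone).

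For polarization within a genotype there is again 1 array per condition. In wild type cells Tbx21 was 2.71 higher in Th1 than in Th2 cultures on the log2 scale, Ifng 1.19 higher and Il4 differed by -3.47. In Ezh2 KO cells the same differences were 0.94, 0.33 and -1.56, whereas Il5 gave -0.74 in wild type and -4.92 in Ezh2 KO, and Il10 -0.38 and -3.43. Th1 minus Th2 differences of 2-fold or more numbered 773 in wild type and 704 in Ezh2 KO. Th1 minus unpolarized gave 701 and 593, and Th2 minus unpolarized 710 and 752. The Th1 minus Th2 differences of the 2 genotypes correlated weakly across genes (Pearson r = 0.12, Spearman rho = 0.16). In wild type, Oasl2, an interferon response gene, was 3.16 higher in Th1 than in Th2 cultures, and Il4 was 3.24 higher in Th2 than in unpolarized cultures. In Ezh2 KO, Col18a1 (5.13), Il5 (3.88), Il10 (3.78) and Cyp11a1 (3.73) led the Th2 minus unpolarized differences. Several of these sizes are uncertain. In wild type, Ifng, Il5 and Il10, Il4 in Th1 and unpolarized and Oasl2 in Th2 cultures read under the low-signal limit. So did Col18a1 in unpolarized and Il5 in unpolarized and Th1 Ezh2 KO cultures. The difference of the genotype effect between Th1 and Th2 cultures had no degrees of freedom for a test. It was 2-fold or more for 1190 genes, among them the core gene Il5, at 0.57 in Th1 and 4.76 in Th2 cultures. Of these 4 Il5 readings only that of Ezh2 KO Th2 was above the low-signal limit. The gap of Il13 is a bound, because its wild type Th2 reading was at the floor, so Il5 and Il13 cannot be ranked.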

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

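The tests of CD8 T cells, of NK cells by themselves and of a batch at labelling or hybridization were chosen after the results were seen, and the predictions of the other tests were written before their values were computed.

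For Il13 the 2 genotypes went opposite ways between Th1 and Th2 cultures: Th1 minus Th2 was 1.03 in wild type, where the Th1 reading was under the low-signal limit and the Th2 reading at the floor, and -3.01 in Ezh2 KO, a gap of 4.04 on the log2 scale. The Ezh2 KO minus wild type difference had opposite signs in Th1 and Th2 cultures for 9 named genes. Hrct1 (3.16 and -1.62, a gap of 4.77), Bcam (2.06 and -2.57, 4.63), Wbp2nl (2.02 and -2.60, 4.62), Gapdhs (3.09 and -1.43, 4.52) and Cilp2 (2.67 and -1.71, 4.37) were higher in Th1 and lower in Th2 cultures. Vgll2 (-3.09 and 2.31, a gap of -5.41), Sct (-2.14 and 2.50, -4.64), Crybb3 (-1.82 and 2.40, -4.22) and Tesmin (-1.74 and 2.46, -4.21) ran the other way. Each of these 9 genes had a reading under the low-signal limit in both cultures, so the signs and gaps are not firm, and with 1 array per group none of the differences was tested.

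Probe sets with no single gene symbol, which no comparison used, carried signal too. Tested singly, 122 of 4451 were higher and 133 lower in Ezh2 KO, 13 and 1 of them by 10-fold or more. The highest rose by at least 5.19 and the lowest fell by 3.82.

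The first pattern is the number of genes that differ by genotype, and the 6 arrays can be split into 3 and 3 in only 10 ways, and only 3 of the 9 other splits exchange labels within cultures and keep the pairing, too few for a share under 0.05. The genotype split gave 1890 genes and the highest of the other splits 0, so that 1 of the 10 splits gave as many. For gene lists 1 of the 10 splits gave as many as the real one, with 15 lists for genotype and up to 12 in the others. The 3 that keep the pairing gave 4, 11 and 6 lists. Their contrasts still hold part of any genotype effect shared by the cultures, so these counts are not a chance level. How many lists chance would call under the preset correlation therefore stays unknown, and the list calls remain weak evidence. Regrouping the arrays puts part of the genotype effect into the residual spread of the fit. The 0 gene calls of the other splits were thus close to fixed and do not make the gene counts firmer. A batch at labelling or hybridization that followed genotype would part the spiked-in controls by genotype, but all 9 of the other splits had control differences at least as large as the genotype split, whose median absolute difference over 42 control probe sets was 0.0489. That argues against such a batch, but not against differences between mice, sorts or culture days that precede labelling.

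The second pattern is the rise of cytotoxic and NK receptor genes. Signal shared between related genes is argued against by 10 of the 15 members that rose being read by probe sets with the plain suffix, among them genes outside the granzyme family. NK cells stay open: Tyrobp, at a mean difference of -0.42 and under the low-signal limit on all Ezh2 KO arrays, met the bound set against them, as Nkg7 read from 7204 to 9208 there. But Tyrobp and Ncr1 read at background on all 6 arrays, where a dim probe set by itself excludes nothing. NK or NKT cells stay open too: the median of its markers, 2.88, was as high as that explanation predicts, but only 2 of 8 could be tested. Cd160 is also among the inhibitory receptors. Fcer1g read under the low-signal limit on all wild type arrays, so it entered the test only through its Ezh2 KO readings. The other markers with a probe set, Tyrobp, Ncr1, Klra8, Klre1 and Zbtb16, read under that limit on all 6 arrays. CD8 T cells predicted Cd8a higher in Ezh2 KO in every culture, and this failed. Cd8a (-0.49) was lower in each, at 78.6, 90.9 and 89.3 in the Ezh2 KO unpolarized, Th1 and Th2 cultures. Those readings are low, other Cd8a probe sets went both ways and Cd8b1 (0.35) was higher on average, so CD8 T cells were not excluded. The purification of naive CD4 T cells named in the labels is meant to exclude both cell types. Loss of Ezh2 in the CD4 T cells themselves remains a candidate explanation that these arrays did not test.

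The third pattern is the joint rise of Th1 and Th2 cytokine genes. Mast cells or basophils, which the purification is meant to exclude, may add Il4 and Il13: their markers had a median of 1.16 over 3 tested members, but these went both ways and Fcer1a and Ms4a2 stayed dim, so that test decided nothing. More recent activation of the Ezh2 KO cells predicted a median of the activation induced genes of at least 0.5 in every culture, and its absence one under 0.25 in every culture. The median was 0.23, with 0.29, 0.09 and 0.23 per culture, so neither held in all 3, and the list passed with the mean of all probe sets of a gene (adjusted p = 0.00152), though not on the main values with an estimated correlation (adjusted p = 0.414) or fry (adjusted p = 0.052). Both explanations stay open, as does a direct effect of genotype.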

How the results depend on the processing

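Over all alternatives, 142 values that answer a comparison were unchanged, 72 moved, 16 lost and 2 gained a call. Unchanged means the same direction and side of the threshold, a count within 1.5 times, or a correlation within its confidence interval or 1 SD of the 3 between cultures. Of single genes and lists, 1151 were unchanged in this sense, 388 lost and 76 gained a call, and 2 reversed, Cbx7 (0.12) and Ighm (0.10), both with the mean of all probe sets of a gene. The cause of these changes was not tested unless given. The 1890 genotype calls are the least stable count. Without the filter 0 higher and 0 lower genes passed: 18193 genes were tested, the prior degrees of freedom fell from 1.66 to 0.862 and the smallest adjusted p was 0.0769. With 1 culture pair left out (1 residual degree of freedom), 0 to 0 higher and 0 to 0 lower genes passed, with smallest adjusted p values from 0.0803 to 0.11. Lower calls numbered 413 with median centring, which moves the median Ezh2 KO minus wild type difference in unpolarized cultures from -0.06 to 0.11 and the share of higher calls from 51.1% to 67.8%. With the mean at or above the 60th percentile there were 1349 higher and 1879 lower calls, with no culture block 1571 lower, and with a trended robust prior 1803 higher and 2306 lower. That prior also gave 31 genes for Th1 against Th2 and 13 for Th2 against unpolarized. Quantile normalization gave 999 higher and 844 lower, and 1745 of the main calls remained. Ezh2 stayed lower in each: -0.47 with median centring (adjusted p = 0.0922), -0.52 without the filter (adjusted p = 0.0881) and from -0.56 to -0.46 without 1 pair (adjusted p = 0.14 to 0.167). With an estimated correlation, 0 lists passed for genotype and 0 for Th1 against Th2; fry gave 14 and 0. For Th1 against Th2, 4 lists passed without the filter and 5 with the mean of probe sets.

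Counts at 2-fold changed with the filter, the floor and the rule for probe sets, and the cause was not tested. Ezh2 KO against wild type gave, higher and lower, in unpolarized, Th1 and Th2 cultures, 1528 and 1761, 1640 and 1309, and 1968 and 1657 without the filter. The same counts were 446 and 199, 378 and 202, and 531 and 316 at the 60th percentile, and 1653 and 1927, 1755 and 1212, and 2223 and 1890 with each probe set by itself. Polarization counts are given as Th1 against unpolarized, Th2 against unpolarized and Th1 against Th2, wild type first. They were 2369, 2490, 2428 and 2161, 2413, 2273 without the filter, and 109, 88, 148 and 26, 111, 101 at the 60th percentile. They were 348, 375, 409 and 235, 439, 410 with the floor at the 40th percentile, and 1707, 1727, 1786 and 1546, 1898, 1793 with each probe set by itself. The difference between Th1 and Th2 cultures in the genotype effect reached 2-fold for 3675, 249 and 3160 genes without the filter, at the 60th percentile and by probe set. The correlation of the genotype difference between cultures (unpolarized with Th1, unpolarized with Th2, Th1 with Th2) was 0.38, 0.42 and 0.43 without the filter, 0.84, 0.86 and 0.85 at the 60th percentile, 0.58, 0.62 and 0.64 without a floor, 0.72, 0.74 and 0.75 with the higher floor, and 0.54, 0.58 and 0.59 by probe set; the first was 0.65 with the mean of probe sets. That of Th1 minus Th2 between genotypes was 0.04, 0.26, 0.16 and 0.10 without the filter, at the 60th percentile, with the higher floor and by probe set.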

Other observations

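The tests of gene families, of the stretch around Ezh2 and of neighbours without shared first letters were chosen after the results were seen, while the predictions for silent and expressed genes and for neighbouring genes were written before their values were computed.

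Beyond the lists, whole gene families stood out. Of 352 families of genes that share a name up to its first digit, a rule that leaves granzyme and Klr genes ungrouped, tested for enrichment among the calls, 2 passed (hypergeometric test, adjusted p = 0.002837 and 0.01286): the Gimap family of immune GTPases, with 6 of 8 members higher in Ezh2 KO, and the Serpinb family of intracellular protease inhibitors, with 5 of 7. This test takes genes as independent, but several members of each family lie side by side, where genes were often called together. The p-values may therefore be too small. The medians of both families (0.75 and 1.80) stayed above 0 with median centring and with quantile normalization, but with median centring only 4 of the 8 Gimap genes passed, and the enrichment was not tested again there. Serpinb9, an inhibitor of granzyme B, rose by 2.02 ± 0.11 and Serpinb9b by at least 3.58 ± 0.95. Of 8 S100a calcium-binding protein genes 4 rose (adjusted p = 0.298 for the family), with S100a4 up by 4.78 ± 0.37 and S100a6 by 2.16 ± 0.01. Metallothioneins Mt1 (1.44 ± 0.42) and Mt2 (1.86 ± 0.49) also rose. In wild type cells the interferon response list was higher in Th1 than in Th2 cultures, with a median of 1.39, while in Ezh2 KO it was -0.01, a contrast that was not tested. Counting 12 genes, Ahr, Cdkn2a, Cdkn2b, Coch, Gcnt2, Gzma, Gzmd, Ifng, Igsf5, Il10, Tmem163 and Upp1 were under an intensity of 64.43 on all wild type arrays and above 257.7 on all Ezh2 KO arrays.

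Only Morc1 did the reverse of these 12 genes, and exchanging the genotype labels within any 1 culture gave 0 such genes either way, a comparison in which the 12 genes themselves could not count again. This is consistent with the hypothesis that loss of Ezh2 raised silent genes more often than it ended the expression of active ones, but histone marks were not analysed here, and indirect effects would look alike.

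Genes that rose also lay side by side. Among 11551 tested genes placed in RefSeq order, 156 adjacent pairs that do not share a family name were both higher in Ezh2 KO, against a median of 77 and a highest value of 108 in 10000 permutations among genes of like expression (one-sided permutation p = 0.0001, the smallest they can give). Pairs that were both lower numbered 107 against a median of 71 in the same permutation test (one-sided permutation p = 0.0001), so the excess is not limited to rises. The name rule keeps pairs of granzyme or Klr genes, but with all pairs that share their first 3 letters left out, 151 higher pairs remained against a median of 77 and a highest value of 107. The longest runs of higher genes had 5 members: Gzme, Gzmd, Gzmg, Gzmf and Gzmc on chromosome 14, a run with Klrd1, Klrk1, Klrc1 and Klra5 on chromosome 6, and a run of Gimap5, Gimap3, Tmem176b, Tmem176a and Gpnmb on the same chromosome. A change shared by neighbouring genes that are not of one family may account for part of the calls.

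The last run lies close to Ezh2 itself, with 16 tested genes between Ezh2 and the nearest Gimap gene. A candidate explanation is DNA of another strain around the targeted Ezh2 gene, carried along with the modified allele, since all samples are labelled C57BL/6 and the origin of the allele is not given in the labels. With the Gimap genes left out, 28 of the 100 tested genes around Ezh2 were called, 20 higher and 8 lower. Other stretches of 100 genes had a median of 16, a 95th percentile of 23 and a highest value of 30, and 7 of 941 overlapping stretches had as many. The stretch includes Ezh2 itself, and a regional effect of Ezh2 loss would look the same, so the Gimap result remains open to both.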
